A study of Mus musculus with 4 samples.

How the data were processed

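The deposited files hold raw HTSeq counts per gene symbol, 1 file for each of 4 libraries, with 22609 gene symbols and 5 tally rows that name no gene. The authors prepared total RNA libraries from hippocampus and sequenced 50 bp single-end reads, per the labels' protocols. Reads were converted with bcl2fastq, aligned to mm9 with TopHat2 2.0.8b and counted with HTSeq, per the submitters' processing notes. The series' design text says that the libraries were run in duplicate, that reads were combined before alignment, and that DESeq followed. The strand setting, the gene annotation and the HTSeq version are not given in the sources used here.

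The tally rows stayed out of library sizes and tests. They held 46.37% and 45.59% of all entries in the controls and 45.17% and 47.3% in the knockouts, mostly alignments at several places (35.73% to 37.35%) and reads outside genes (8.74% to 9.679%). Gene counts summed to 33495548 and 33235564 in the FLOX controls and to 34878375 and 27930696 in the knockouts. CPM was computed from the counts with TMM factors, which ran from 0.9837 to 1.01. A floor of 3 counts gives the level that a count of 0 allows, and the ratio of Cyp19a1 has a 95% counting interval.

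Groups were taken from the sample titles. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 15011. The test was edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit used legacy=FALSE, since the alternatives fixed beforehand name legacy=TRUE, the default of this version. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and two-sided p, adjusted over the 30 of 32 lists with at least 3 tested members. Camera was repeated with an estimated correlation, which leaves 2 residual degrees of freedom, and with fry. The lists cover reactive and homeostatic astrocytes, JAK-STAT3 and FGF signaling, estrogen, inflammation, neurotrophic factors, immediate-early genes, stress responses, extracellular matrix, and markers of other cell types and neighboring tissues.

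The lists, the design, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Cyp19a1, Gfap, Stat3, Fgf2 and Fgfr3; the 6 largest rises and 6 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and both knockout values on the same side of both controls; the 2 members with the smallest p of each core list; the member with the smallest p of each list of stress or matrix genes; and the most abundant tested member of each cell type list. This gave 54 genes; some items are not reported here. Other members, such as Lcn2, Aqp4, Gjb6, Itgam, Cd68, Ndst4, Tdo2, Prox1, Ermn, Acta2, Il6ra, Cntfr, Fosb and Npas4, were named after their values were seen.

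The steps were tested on simulated counts with 200 changed genes among 14852 tested. For the comparison of GFAP-ARO-KO with FLOX control, 36% of 1.5-fold, 74% of 2-fold, 94% of 4-fold and 98% of 8-fold changes were recovered, with 50 genes at each size. With gene-wise dispersions, 16.6% of the calls were unchanged genes, above the nominal rate; with trended dispersions it was 6.17%. Unadjusted p under 0.05 was found for 5.21% of unchanged genes. The simulation changed 200 of 14852 genes, whereas 20.4% of tested genes were called in the data. These rates of recovery and error therefore need not hold for the data.

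Coordinates and transcripts come from NCBIM37, the assembly that mm9 is built on, with GENCODE vM1, which held 14641 of the tested symbols once. Windows of 50 bases were searched in the whole genome on both strands, counting exact matches only. This was done for each named or strongly changed gene with a protein-coding transcript and a single position. Alternatives were RLE and upper-quartile scaling, no and stricter filters on low counts, legacy and non-robust estimation, limma-voom, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. Offsets for GC content and length, a gene set without predicted, clone-named and ribosomal genes, and a covariate of meningeal markers were chosen after seeing the data. The meningeal markers were high mainly in the second knockout library, so the covariate acts much like leaving that library out. Groups of 2 are too small for a test of outlying samples.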

Results

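RNA sequencing measured gene expression in the hippocampus of ovariectomized female mice 24 h after 20 min of global cerebral ischemia, produced by closing both common carotid arteries. Libraries came from 2 FLOX control samples, which carry the floxed aromatase gene and keep the enzyme, and from 2 GFAP-ARO-KO samples, in which Cre under the Gfap promoter deletes Cyp19a1 (aromatase, the enzyme that makes estrogen from androgens) in astrocytes. The control libraries held 33495548 and 33235564 reads assigned to genes, and the knockout libraries 34878375 and 27930696. A count of 0 in 1 library allowed a level of up to 0.0896 and 0.0903 CPM (read counts scaled by library size) in the controls and 0.086 and 0.107 CPM in the knockouts. The libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 14.4 between the controls and 27.2 between the knockouts. Each was counted as 1 sample, although such a spread does not show that the libraries came from separate animals. The first principal component held 74.8% of the variance of log2 CPM and separated the genotypes, with scores of -38.4 and -41.3 in the controls and 33.0 and 46.8 in the knockouts.

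The targeted gene could not check the genotype labels. Cyp19a1 (chromosome 9, 54013744 to 54115917, minus strand, mm9) gave 3 and 2 reads in the controls and 1 and 9 reads in the knockouts, too few to be tested. The ratio of knockout to control was 2.12, with a 95% counting interval of 0.662 to 7.92, and 0.383 without the second knockout library. Xist gave 10410 and 9403 reads in the controls and 11961 and 12661 in the knockouts, and Ddx3y, Uty, Eif2s3y and Kdm5d gave 0 reads in all 4 libraries.

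The comparison asked how the ischemic hippocampus differs between mice labelled as astrocyte aromatase knockouts and FLOX controls. Estrogen was not measured. All 4 libraries came after ischemia, without a sham group. A changed response to ischemia thus cannot be told apart from a difference present before it. Nor can it be told apart from ischemia of unequal strength between the groups, which the read counts do not measure. In the knockout 5 of 13 pan-reactive astrocyte genes fell and 1 rose, 8 of 16 genes of JAK-STAT3 signaling fell and 2 rose, 6 of 13 inflammatory genes fell, and 11 of 14 markers of microglia fell. These 4 lists were lower by camera with a preset correlation between genes. None passed with an estimated correlation (smallest adjusted p = 0.386). That test has only 2 residual degrees of freedom, so not passing it does not show that correlated genes account for a list's fall. With fry, which asks whether a list moves, none of the 4 passed (adjusted p from 0.0609 for microglia to 0.115 for inflammatory genes). Gfap, the intermediate filament protein of astrocytes, was 1.91-fold lower, at 1407 ± 40.4 CPM in the controls and 735 ± 36.7 CPM in the knockouts (SD, n = 2 each). Timp1, a metalloprotease inhibitor, was 38.3-fold lower, Lif, a cytokine that activates STAT3, was 16.8-fold lower, and the chemokine gene Ccl12 was 107-fold lower. Fkbp5, a co-chaperone of the glucocorticoid receptor, was 1.91-fold higher, and Cdkn1a, an inhibitor of the cell cycle, was 5.44-fold higher. Of 15011 genes tested with edgeR's quasi-likelihood test, 3061 had a Benjamini-Hochberg adjusted p under 0.05, of which 1409 were higher and 1652 lower in the knockout. At least a 2-fold change was seen for 515 of the higher and 501 of the lower genes. The number of calls fell to 901 without the first control library and to 814 without the second, and rose to 4820 without the first knockout library.

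**Figure D1:**
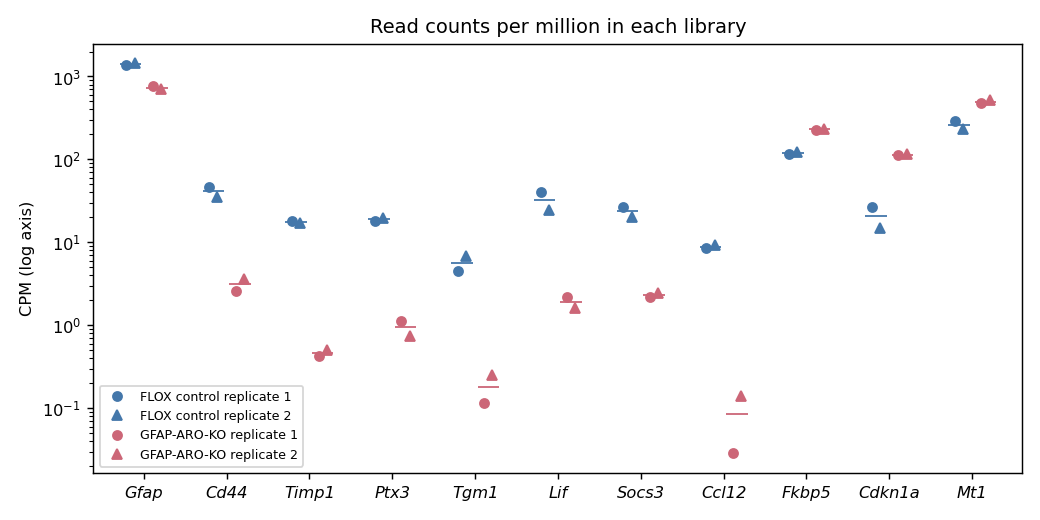
CPM (log axis) of 11 of the genes named in the text in each of the 4 libraries; symbols are libraries and horizontal lines are group means. Both knockout libraries lie below both controls for Gfap, Cd44, Timp1, Ptx3, Tgm1, Lif, Socs3 and Ccl12, and above both for Fkbp5, Cdkn1a and Mt1.

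Among 13 pan-reactive astrocyte genes, 5 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone. Timp1 fell by 5.26 ± 0.24 (log2 fold change ± SE, adjusted p = 2.43e-04), and Cd44, a hyaluronan receptor, fell by 3.73 ± 0.22 (adjusted p = 4.04e-04). Gfap fell by 0.94 ± 0.09 (adjusted p = 0.00151), whereas Lcn2, which encodes lipocalin 2, rose by 2.64 and was highest in the second knockout library, at 25.5 CPM against 9.57 in the first. Lcn2 did not pass without the first control (adjusted p = 0.219) or the second (0.293), where 0 members of the list rose, and 2 rose without the first knockout library. The list was lower by camera (adjusted p = 2.30e-07, and adjusted p = 0.386 with an estimated correlation). Of 12 genes of the A2 reactive state, 7 fell and 5 did not pass, or 8 fell and 1 rose adjusted over the list alone, and 1 also rose without the second control or the first knockout library. Tgm1, a transglutaminase, fell by 5.0 ± 0.47 (adjusted p = 0.00151) and Ptx3, a pentraxin, fell by 4.30 ± 0.23 (adjusted p = 4.04e-04). The A2 list was lower by camera (adjusted p = 1.59e-07, and adjusted p = 0.386 with an estimated correlation). Of 11 tested genes of the A1 state, 2 rose, 2 fell and 7 did not pass, or 2 rose and 3 fell adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.627). Without the first knockout library 6 of them rose, without the first control 1 rose and 1 fell, and without the second control 1 rose and 0 fell. Fkbp5 rose by 0.93 ± 0.09 (adjusted p = 0.00178) and Amigo2, an adhesion protein, fell by 1.02 ± 0.19 (adjusted p = 0.0127, and 0.0725 without the second control library). In the annotation Timp1 overlaps Syn1, Ptx3 overlaps Veph1, Amigo2 overlaps Fam113b and Gfap overlaps a predicted gene. The strand setting of the counting is not given in the sources used here, so overlapping genes could share reads.

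Genes of homeostatic astrocytes went both ways. Of 13, 2 rose, 3 fell and 8 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.884; without either control library 1 rose and 1 fell. The water channel gene Aqp4 fell by 1.40, and the connexin gene Gjb6 rose by 1.11. Slc1a2, the main astrocyte glutamate transporter, was at 2894 ± 120 CPM in the controls and 2592 ± 128 CPM in the knockouts (SD, n = 2 each; adjusted p = 0.222).

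Among 16 tested genes of JAK-STAT3 signaling, 8 fell, 2 rose and 6 did not pass, or 9 fell and 2 rose adjusted over the list alone. Lif fell by 4.07 ± 0.32 (adjusted p = 0.00122), and Socs3, the feedback inhibitor that STAT3 induces, fell by 3.35 ± 0.22 (adjusted p = 5.69e-04). Stat3 itself had a log2 fold change of -0.35 ± 0.13 and did not pass (adjusted p = 0.0882). It was at -0.205 without the first knockout library and at -0.503 without the second, so its size depends on which knockout library is kept. With a covariate of meningeal markers chosen after seeing the data it was at -0.471 and passed (adjusted p = 0.0246). Those markers were high mainly in the second knockout library, so the covariate fit and the fit without that library are not separate support. The gene overlaps Stat5a. The list was lower by camera (adjusted p = 2.09e-05, and adjusted p = 0.386 with an estimated correlation). Only 4 members fell without the first control library and 5 without the second, and 0 rose without either. The receptor genes Il6ra (rose by 0.75 ± 0.17) and Cntfr (rose by 0.38 ± 0.10) did not pass without either control (adjusted p from 0.129 to 0.185). Of 15 genes of FGF signaling, 7 fell, 1 rose and 7 did not pass, or 9 fell and 1 rose adjusted over the list alone. The feedback inhibitors Dusp6 and Spry2 fell by 0.99 ± 0.15 (adjusted p = 0.00603) and 0.92 ± 0.12 (adjusted p = 0.00377). The receptor gene Fgfr3 rose by 0.48 ± 0.14 (adjusted p = 0.0467), a call that was lost without the first control (adjusted p = 0.126), the second control (0.233) or the first knockout library (0.0777), as well as with no filter on low counts (0.0529) and with limma-voom (0.0542). Fgf2, at 0.59 ± 0.07 CPM in the controls and 0.72 ± 0.27 CPM in the knockouts (SD, n = 2 each), did not pass (adjusted p = 0.621). It overlaps Nudt6, Bbs12 and Cetn4, with which it could share reads. The FGF list was lower by camera (adjusted p = 0.00569, and adjusted p = 0.464 with an estimated correlation), but 2 members fell without the first control library and 3 without the second.

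Of the genes of estrogen synthesis and response, by edgeR 0 of 10 tested members passed over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 1. Srd5a1, a steroid 5-alpha reductase whose gene overlaps Nsun2, had a log2 fold change of -0.77 ± 0.24 (adjusted p = 0.0552). It passed with DESeq2 (0.0394), without the second knockout library (0.0428), and with offsets for GC content and length (0.0475) or the meningeal covariate (0.0474), the last 2 chosen after seeing the data. Hsd17b12 had a log2 fold change of -0.26 ± 0.09 (adjusted p = 0.0879). The camera adjusted p was 0.700. Of 11 tested neurotrophic factor genes, 2 fell, 1 rose and 8 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.439. Without the first control library 0 fell and 0 rose, without the second 1 fell and 0 rose, without the first knockout 4 fell and 2 rose, and without the second knockout 2 fell and 0 rose. Bdnf, a growth factor of neurons, fell by 0.97 ± 0.19 (adjusted p = 0.0175, and 0.0950 without the first control library). The transcription factor gene Crem fell by 0.89 ± 0.16 (adjusted p = 0.0105, with 0.0724 and 0.0863 without the first and the second control library).

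Of 13 tested cytokine, chemokine and adhesion genes, 6 fell and 7 did not pass, or 8 fell adjusted over the list alone. Ccl12 fell by 6.74 ± 0.42 (adjusted p = 4.04e-04), from 284 and 303 reads in the controls to 1 and 4 in the knockouts, and Ccl2 fell by 5.33 ± 0.63 (adjusted p = 0.00264), from 69 and 109 reads to 1 and 3. The list was lower by camera (adjusted p = 9.63e-07, and adjusted p = 0.458 with an estimated correlation), and 2 members fell without the second control library. Of 14 markers of microglia and macrophages, 11 fell and 3 did not pass, or 12 fell adjusted over the list alone. The integrin gene Itgam fell by 1.97 ± 0.23 (adjusted p = 0.00316), while Cd68 had a log2 fold change of -0.12, and of 0.14 without the second knockout library. The microglia list was lower by camera (adjusted p = 1.94e-12, and adjusted p = 0.386 with an estimated correlation). Of 15 tested interferon-stimulated genes, 4 fell and 11 did not pass, also when adjusted over the list alone, led by Xaf1, which fell by 2.79 ± 0.19 (adjusted p = 6.39e-04). Interferon genes were lower by camera (adjusted p = 2.71e-04, and adjusted p = 0.765 with an estimated correlation), with 2 falling without either control library and 9 without the second knockout library. Of the markers of infiltrating leukocytes only Lyz2 could be tested, and it did not pass (log2 fold change -0.39 ± 0.25, adjusted p = 0.302). With the meningeal covariate Lyz2 did pass (log2 fold change -0.68, adjusted p = 0.0448), and its log2 fold change was -0.07 without the first and -0.73 without the second knockout library.

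Of 18 immediate-early genes, which neurons switch on with activity, 8 fell and 10 did not pass, also when adjusted over the list alone. Atf3 fell by 2.11 ± 0.28 (adjusted p = 0.00427) and Nr4a2 fell by 1.02 ± 0.16 (adjusted p = 0.00649), whereas Fosb had a log2 fold change of 0.28 ± 0.47 and Npas4 of -0.02 ± 0.20. Both signs changed with a library left out, to -0.50 for Fosb without the first knockout and 0.19 for Npas4 without the first control. This list was lower by camera (adjusted p = 1.55e-04, but adjusted p = 0.764 with an estimated correlation), with 5 members falling without the first control library and 4 without the second knockout library. Of 14 heat shock and unfolded protein response genes, 6 fell and 8 did not pass, also when adjusted over the list alone, and 3 fell without either control library. Bag3, a co-chaperone, fell by 1.12 ± 0.13 (adjusted p = 0.00328), and the list was lower by camera (adjusted p = 0.00829, and adjusted p = 0.386 with an estimated correlation).

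Most markers of neurons did not pass. Of 11 tested markers of excitatory neurons 2 fell and 9 did not pass, and of 11 markers of inhibitory neurons 2 fell and 9 did not pass, with the same counts adjusted over each list alone and camera adjusted p of 0.607 and 0.285. None of these falls was called without the first or without the second control library, and 1 in each list was without the second knockout library. Camk2a was at 5302 ± 494 CPM in the controls and 4669 ± 7.33 CPM in the knockouts (SD, n = 2 each; adjusted p = 0.188), and Gad1 had a log2 fold change of -0.03 ± 0.10 (adjusted p = 0.876). Of 8 CA1 markers, 3 fell and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00362, and adjusted p = 0.386 with an estimated correlation). Ndst4 fell by 1.72 while Mpped1 had a log2 fold change of -0.07 ± 0.09 (adjusted p = 0.581). Of these markers 1 rose without the first control library. Of 9 dentate gyrus markers, 4 rose and 5 did not pass, or 5 rose adjusted over the list alone (camera adjusted p = 0.00209, and adjusted p = 0.386 with an estimated correlation). Tdo2 rose by 2.42 and Prox1 by 0.63, Calb1 had a log2 fold change of -0.24 ± 0.16 (adjusted p = 0.308), and 2 of the 9 rose without the second control library. Prox1 then did not pass (adjusted p = 0.0956), and Tdo2 did not without the first control (0.0850), the first knockout (0.0769) or the second knockout (0.124), or with the meningeal covariate (0.0517). Of 13 oligodendrocyte lineage markers, 7 fell and 6 did not pass, or 9 fell adjusted over the list alone (camera adjusted p = 2.23e-06, and adjusted p = 0.386 with an estimated correlation). Ermn, a myelin protein gene, fell by 1.96, whereas Mbp, at 2340 ± 164 CPM in the controls and 2085 ± 32.4 CPM in the knockouts (SD, n = 2 each), did not pass (adjusted p = 0.215). Without the first control library 4 of these markers fell, and without the second 3.

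**Figure D2:**
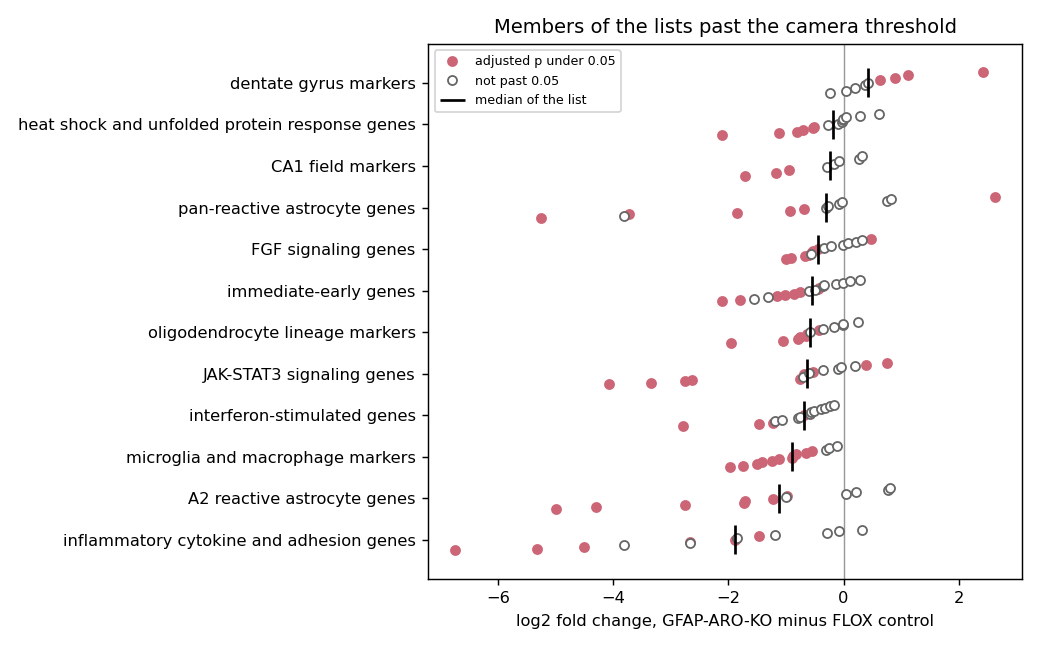
Log2 fold change (knockout minus control) of each tested member of the 12 lists past the camera threshold; filled circles passed an adjusted p of 0.05, open circles did not, and black bars are list medians. Medians lie below 0 in 11 lists and above 0 for dentate gyrus markers.

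Tissue lists for regions beside the hippocampus did not pass camera, although single members changed. Slc17a6, a vesicular glutamate transporter of thalamic neurons, fell by 2.90 ± 0.24 (adjusted p = 0.00177). Of 8 thalamus markers 2 fell and 1 rose (camera adjusted p = 0.117, and 3.25e-04 without the second knockout library); 0 rose without that library or either control, and 2 without the first knockout. Of 8 neocortex markers 2 fell and 1 rose (camera adjusted p = 0.545), with 0 and 1 falling without the first and the second control library, and Rprm did not pass (log2 fold change -0.79 ± 0.30, adjusted p = 0.128). Rprm passed without the second control library (log2 fold change -1.17, adjusted p = 0.00971), and without the first it was at -0.27. Of 8 striatum markers 2 rose (camera adjusted p = 0.339, and 0.0113 without the first control library), among them Ppp1r1b, which encodes DARPP-32 and rose by 1.05 ± 0.13 (adjusted p = 0.00335). Without the second control library 1 rose, and without the first knockout 1 fell. The counts over all 4 libraries were the same adjusted over each list alone. Of 8 tested choroid plexus markers 2 rose (camera adjusted p = 0.545), or 2 rose and 1 fell adjusted over the list alone, neither rising without the first or without the second control library. Kl did not pass (log2 fold change 0.19 ± 0.13, adjusted p = 0.324). By edgeR 0 of 8 ependymal markers passed over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and limma-voom and DESeq2 called 0 (camera adjusted p = 0.285). Without the first knockout library 2 of them fell, and without the first control library the list was lower by camera (adjusted p = 0.0288). Foxj1 had a log2 fold change of -0.06 ± 0.21 (adjusted p = 0.872). Of the red blood cell genes only Alas2 could be tested (log2 fold change 0.50 ± 0.30, adjusted p = 0.277).

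Among other stress lists, 3 of 14 apoptosis and p53 target genes rose, or 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.491, and 0.0247 without the first control library). Cdkn1a rose by 2.44 ± 0.26 (adjusted p = 0.00377), but did not pass without the first knockout (adjusted p = 0.105) or the second (0.0536). Only 1 member of the list rose without the second knockout library or either control library, while 2 fell without the second control. Of 12 antioxidant and metallothionein genes 2 rose and 1 fell, or 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.553). Without the first knockout library 5 rose and 2 fell, without the second 2 fell, and without either control 1 rose and 0 fell. Mt1, a metallothionein, rose by 0.93 ± 0.13 (adjusted p = 0.00502). Of 12 hypoxia-inducible genes 3 fell and 1 rose, or 4 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.407). Without the first control library 0 fell and 2 rose, without the second 1 fell and 0 rose, and without the first knockout 2 rose. P4ha1, a prolyl hydroxylase of collagen, fell by 0.87 ± 0.15 (adjusted p = 0.010, with 0.0502 and 0.0539 without the first and the second control library). Of 14 tested extracellular matrix and scar genes 3 rose and 2 fell, or 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.884), and Tnc, which encodes tenascin C, fell by 1.95 ± 0.20 (adjusted p = 0.00192). In that list 0 rose without either control library and 5 without the first knockout, and 4 fell without the second knockout and 1 without the first control. The median had another sign than the mean and the camera direction in the lists of apoptosis, antioxidant, homeostatic astrocyte, excitatory neuron and striatum genes. In the extracellular matrix list the median (0.027) and the mean (0.217) both had another sign than the camera direction, which was down.

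The second knockout library stood apart in genes of meninges and vessel walls. Of 19 tested markers of meningeal fibroblasts and mural cells, 18 were higher there than in the first knockout library. Igf2, a growth factor gene of the meninges, was at 25.8 and 37.0 CPM in the controls and 27.7 and 224.7 CPM in the knockouts, and Acta2, the actin of smooth muscle, was at 8.19, 6.82, 14.9 and 113.7 CPM. By edgeR 1 of 10 meningeal markers rose, also when adjusted over the list alone. The list did not pass camera (adjusted p = 0.167, and adjusted p = 0.795 with an estimated correlation, which was 0.959). The median log2 fold change of the meningeal list was 1.396 over all 4 libraries and 2.22 without the first knockout library. Of 9 mural cell markers 1 rose, or 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. The list did not pass camera (adjusted p = 0.285, and adjusted p = 0.795 with an estimated correlation, which was 0.337). Its median log2 fold change was 0.493 over all 4 libraries and 0.724 without the first knockout library. Between settings on all 4 libraries the count of mural markers that rose ran from 0 to 3. It was 3 with DESeq2, with edgeR without robust estimation and with the meningeal covariate. It was 0 with no filter on low counts, limma-voom, offsets for GC content and length, or without predicted, clone-named and ribosomal genes. Igf2, which overlaps an antisense gene, did not pass (log2 fold change 2.00 ± 1.20, adjusted p = 0.338), nor did Vtn (0.49 ± 0.33, adjusted p = 0.344). Without the first knockout library both passed, Igf2 at 2.84 (adjusted p = 0.00167) and Vtn at 0.92 (adjusted p = 1.01e-04), and without the second they were at -0.17 and -0.10 and did not pass. Acta2 did not pass (log2 fold change 3.09 ± 1.26, adjusted p = 0.201), but did without the first knockout (3.92, adjusted p = 2.73e-08) and without the second (1.00, adjusted p = 0.00720). Over all 4 libraries Acta2 also passed in edgeR without robust estimation (adjusted p = 0.0413) and with the meningeal covariate (1.32, adjusted p = 0.0125). Of 12 endothelial markers 2 rose and 1 fell, or 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.285). Without the first knockout library 7 rose (camera adjusted p = 0.0137), and without the second 2 fell. Slco1a4 did not pass (log2 fold change 0.49 ± 0.19, adjusted p = 0.117), although it did without the first knockout (0.76, adjusted p = 6.23e-04) and was at 0.17 without the second. Without the second knockout library, 2763 genes were called.

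**Figure D3:**
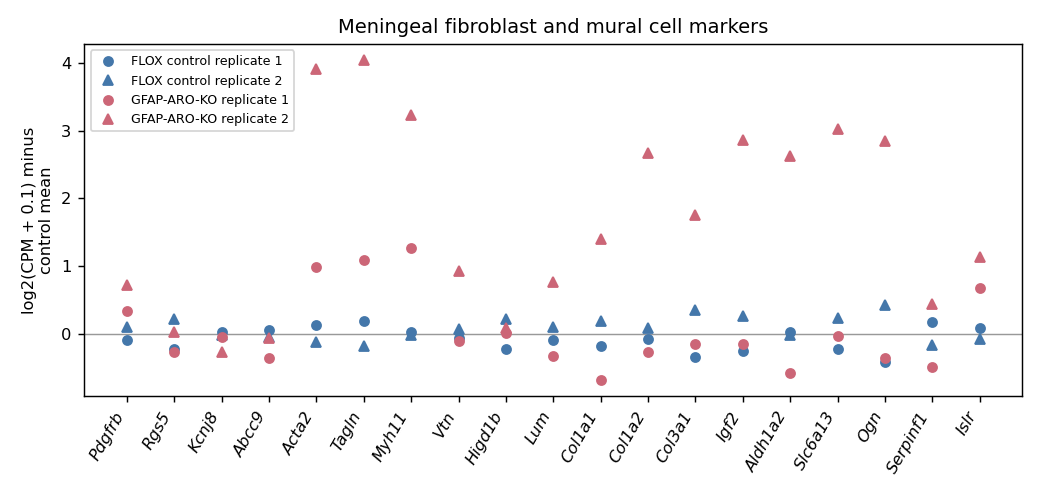
Log2(CPM + 0.1) of 19 markers of mural cells (Pdgfrb to Higd1b) and meningeal fibroblasts (Lum to Islr) in each library, less the mean of the controls; symbols are libraries. The second knockout library exceeds the first for 18 of the 19 markers.

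The largest rises by the fixed rule were those of Eif3j (6.54 ± 0.54 on the log2 scale, adjusted p = 9.70e-04), Pttg1 (6.0 ± 0.27, adjusted p = 2.43e-04), Bub1b (5.35 ± 0.44, adjusted p = 0.00108), Rpl3 (5.34 ± 0.21, adjusted p = 1.81e-04), Wnt10b (5.07 ± 0.37, adjusted p = 9.70e-04) and Rpl29 (4.72 ± 0.41, adjusted p = 0.00122). Eif3j had 5 and 0 reads in the controls and 227 and 237 in the knockouts, so its fold rests on few control reads. Pttg1 encodes securin and Bub1b a checkpoint kinase, both of mitosis, and Wnt10b a secreted ligand. Of the 50-base windows of their transcripts, 83.2% for Eif3j, 91.2% for Rpl3 and 86.0% for Rpl29 also occur elsewhere in the genome, so the counts of these 3 genes are uncertain, and Eif3j overlaps Spg11. Besides Timp1, Tgm1, Ptx3 and Ccl12, the largest falls were those of Gdpd3 (fell by 5.92 ± 0.35, adjusted p = 4.04e-04) and AA465934 (fell by 4.32 ± 0.24, adjusted p = 4.04e-04).

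In all, 12 of 30 lists had a camera adjusted p under 0.05 with a preset correlation between genes of 0.01, 11 of them lower and 1 higher in the knockout. With an estimated correlation 0 did, and 2 had an unadjusted p under 0.05. The A2 list had an estimated correlation of -0.0487, below the preset, yet its camera p rose from 1.059e-08 to 0.0264. The 2 residual degrees of freedom thus limit this second test, which cannot tell correlated genes from too few samples. In the annotation Gdpd3, Ccl2, Crem, Slc1a2, Gad1, Mbp, Ppp1r1b, Tnc and Alas2 overlap other genes too. Intervals and floors cover counting error only, and since the labels do not say that the replicates are separate animals, p-values measure the spread between these samples.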

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

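Alternatives for GC content and length, for the gene set and for meningeal markers were chosen after the data were seen. No gene called in the main comparison was called with the other sign under any alternative. The number of calls ran from 2752 without predicted, clone-named and ribosomal genes to 3527 with GC and length offsets, apart from the libraries left out. DESeq2 called 3169 genes and gave no adjusted p for 3187. Leaving out 1 library in turn gave 814 (without the second control) to 4820 (without the first knockout) calls, 296 to 2387 of them higher and 518 to 2433 lower; the lone sample is then assumed to vary like the other group, and fewer samples enter the fit. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.0057 across genes, and the replicate block gave 3193 calls, with Rprm then passing and Lcn2 not (adjusted p = 0.0672). Under the block the camera direction of the extracellular matrix list reversed (adjusted p = 0.949).

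With an estimated correlation 0 lists passed and with fry 5 did: A2, heat shock, CA1, dentate gyrus and oligodendrocyte genes (adjusted p from 0.0397 to 0.0481). Fry asks whether a list moves, not whether it moves more than other genes. The pan-reactive, JAK-STAT3, FGF, inflammatory, immediate-early, interferon and microglia lists did not pass it. Counts of called members in short lists moved by over 1.5 times in some other settings on all 4 libraries. Examples follow, with the count in the report in brackets. Without robust estimation 0 neurotrophic genes rose (1). With DESeq2 2 apoptosis genes fell (0), 3 antioxidant genes rose (2) and 2 fell (1), and 1 A2 gene rose (0). With no filter 1 choroid plexus marker rose (2), and with the meningeal covariate 11 interferon genes fell (4). With the replicate block 2 apoptosis genes fell (0), 1 A2 gene rose (0) and 1 inhibitory neuron marker fell (2). The block also left 1 choroid plexus marker rising (2) and 1 falling (0). With upper-quartile scaling 1 excitatory neuron marker fell (2). The 12 called lists kept their call and direction with each library left out, without the filter, with RLE scaling, the block, and GC offsets. With each library left out in turn, 12 to 15 lists passed. Uncalled log2 fold changes reversed in some of these fits: they ran from -0.103 to 0.062 for Gad1, from -0.314 to 0.154 for Foxj1 (0.078 with the meningeal covariate), from -0.438 to 0.141 for Cd68 (0.05 with that covariate), from -0.026 to 0.215 for Nr1d1, from -0.499 to 0.784 for Fosb, from -0.192 to 0.192 for Npas4 (0.008 with upper-quartile scaling), from -0.147 to 0.636 for Fgf2, from -0.098 to 0.922 for Vtn and from -0.171 to 2.839 for Igf2, the last 2 with the lowest value without the second knockout library. The direction of uncalled lists also reversed in some, with adjusted p from 0.263 to 0.899 for extracellular matrix, 0.460 to 0.899 for homeostatic astrocyte, 0.0113 to 0.895 for striatum, 0.0645 to 0.860 for A1, 0.271 to 0.991 for antioxidant and 1.24e-16 to 0.595 for meningeal genes, the smallest striatum and meningeal values being without the first control and the first knockout library. The Cyp19a1 ratio ran from 0.383 without the second knockout library, which holds 9 of its 10 knockout reads, to 4.3 without the first. For the other reversals the cause was not tested. Depth limits Cyp19a1, which has too few reads to be tested.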

Other observations

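A few genes outside the fixed lists were picked after their values were seen. Cirbp, a cold-inducible RNA-binding protein gene, rose by 1.94 ± 0.15 on the log2 scale (edgeR adjusted p = 9.86e-04), from 53.5 and 44.0 CPM in the controls to 165.7 and 207.6 CPM in the knockouts. Its relative Rbm3 rose by 0.94 ± 0.18 (adjusted p = 0.0141), and Cry1, a repressor of the circadian clock, rose by 1.41 ± 0.23 (adjusted p = 0.00961). Without the second control library Rbm3 (adjusted p = 0.121) and Cry1 (0.0619) did not pass.

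All tests in the rest of this part were chosen after the result was seen, except that of the median share of windows found elsewhere in the genome. The higher values of 6 glucocorticoid-induced genes, Fkbp5, Cdkn1a, Hif3a (1.80 ± 0.18, adjusted p = 0.00178), Plin4 (1.41 ± 0.12, adjusted p = 0.00115), Mt1 and Mt2, prompted a test of 9 others. Of these 9, 5 rose and 0 fell, among them Tsc22d3 (1.02 ± 0.19, adjusted p = 0.0139) and Per1 (0.66 ± 0.15, adjusted p = 0.0226). Of the first 6, Mt2 did not pass (adjusted p = 0.0617), although it did with DESeq2 (0.00135), edgeR without robust estimation (0.0492) and without the first knockout library (3.03e-04). Tsc22d3 (adjusted p = 0.0567) and Per1 (0.0601) did not pass without the second knockout library, and Per1 did not without the second control. A different time of day at sampling stays open: Dbp and Nr1d1, clock outputs with a wide daily swing, had log2 fold changes of -0.12 and 0.09, within 0.33 of 0 at 2 standard errors. Yet of 8 clock output genes 2 rose (Per3 and Tef) and 1 fell (Per2), with a median of 0.25 (camera p = 0.183, and p = 0.303 with an estimated correlation), and Cry1 and Per1 rose. Per2, Per3 and Tef were not called without either control library (adjusted p from 0.0689 to 0.178). Higher glucocorticoid signaling in the knockout may account for the higher values of the first 6 genes and also stays open: the 9 others were higher by camera (p = 1.075e-04), but not with an estimated correlation (p = 0.219).

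Fewer microglia as the whole cause of the lower microglia markers is argued against, since the 14 log2 fold changes ran from -1.97 to -0.12 and differed by more than their errors (Cochran's Q of 146, where chance exceeds 22.4 in 5% of cases if genes err independently), and a shift in microglial state, alone or with a change in number, stays open as untested. Meningeal or vessel tissue in the second knockout library is argued against as the cause of the lower microglia markers, of which 12 fell without that library against 11 with it.

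Of 51 genes called beyond 16-fold, 44 have a protein-coding transcript and a single position in the annotation, and the others were not searched for copies. For the 44 as a set, reads shared with exact copies are argued against, since the median share of windows with an exact match elsewhere was 0%. Copies that differ by a base or more in each window would be missed by this search. Of the 44, 9 had over 10%, as had 19 of 176 matched uncalled genes (Fisher's exact p = 0.125, two-sided). For 4 genes (Rpl3, Rpl29, Eif3j and Kpna2), at 83.2% to 92.7%, copies stay open, and genes with over 50% were not shown to be more frequent than among matched genes (4 of 44 against 6 of 176, Fisher's exact p = 0.116, two-sided). A different strain background of the 2 groups, which the labels do not give, cannot be told apart from the genotype: Gabra2 (fell by 2.60) and Nnt (fell by 0.79), both with known deletions in C57BL/6J mice, and Glo1 (fell by 1.20), whose copy number varies between strains, were lower in the knockout (Nnt with an adjusted p of 0.0919 without the second control library). Of the called genes beyond 4-fold, 66.7% lay 0.5 to 5 Mb from another, against a mean of 64.2% in matched draws (permutation p = 0.254 over 10000 draws). Since strain differences spread over the whole genome need not cluster, this result does not weigh against a different background.

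The 4 libraries can be split into 2 and 2 in only 3 ways, of which 1, the real one, called as many as 3061 genes, while the highest other called 0 with edgeR (60 and 64 genes at an unadjusted p under 0.05). So few splits cannot give a share under 0.05.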
